A study of Mus musculus with 6 samples.

How the data were processed

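Expression was measured in primary mouse myoblasts, the proliferating precursors of skeletal muscle fibres, on 6 arrays: 3 control and 3 activated cultures. Per the labels' protocols, cells grew for 5 passages in Ham F10 medium with 20% FBS and bFGF at 2 ng/ml and were then differentiated by serum withdrawal for 24 hours in medium with 2% HS. The cells carried a tamoxifen-inducible Cre recombinase under Pax7 control and 1 beta-catenin allele whose exon 3 is flanked by loxP sites. Activated cultures received 4-hydroxytamoxifen dissolved in ethanol during differentiation and control cultures received ethanol alone, per the labels' protocols. The dose, the exact timing of treatment relative to serum withdrawal and the time between treatment and harvest are not given in the sources used here. Biotin-labelled target was prepared from 100 ng of total RNA with an Affymetrix whole-transcript kit, per the labels' protocols.

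The deposited table holds log2 expression values, and RMA and Partek are named for it in the submitters' processing notes, with no version and no role given. RMA in general corrects background, normalizes probes across arrays by quantiles and summarizes the probes of each probe set on a log2 scale. How it was run, the array design, genome build and detection calls are not given in the sources used here. The identifiers of the 24479 probe sets have the form of Entrez gene numbers. The platform annotation gave exactly 1 gene symbol to 23281 of them, several symbols to 0 and none to 1198. Of the named probe sets, 23156 had their identifier as an Entrez number in the RefSeq gene table (assembly GRCm38.p6), with the same symbol each time. No coordinates are given, since the build behind the probe sets was not named. The deposited values differed in spread between arrays, from an SD of 1.72 to 2.12. A difference in spread between groups moves bright and dim genes in opposite directions.

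From these values, limma 3.58.1 in R 4.3.3 fitted a linear model with group as the only term to the 23281 named probe sets, with moderated two-sided tests and Benjamini-Hochberg adjustment. Where a symbol had several probe sets (2 symbols), the one with the highest mean over the 6 arrays was used, leaving 23279 genes. No filter on dim genes and no pseudocount was applied. Errors of group means are SDs over 3 cultures, and errors of differences are limma's standard errors. The labels state that RNA came from 3 independent cultures per condition. They do not say whether the cultures came from different animals, so p-values measure the spread between these cultures. The number of arrays limits the precision. In simulated data for activated against control, 50 genes per size were changed among 23279 genes, with the fitted variance of each gene. The fit recovered 8% of genes changed 2-fold, 78% of those changed 4-fold, 98% of those changed 8-fold and 100% of those changed 16-fold. It called 7 unchanged genes. The simulated genes varied independently, without pair effects, and changes of all sizes were planted together. These shares therefore need not hold for the real data, where Timp3 differed 21.1-fold and did not pass (limma, adjusted p = 0.0848).

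Replicate numbers are shared between the groups. Deviations from the group means correlated across genes at 0.38 for the arrays numbered 1, at 0.49 for those numbered 2 and at 0.45 for those numbered 3. Centring on the group means makes the differently numbered combinations negative on balance, so they add nothing to this check. By the criterion set before the data were examined (every pair above 0.1), the numbers were taken to pair the arrays. The check used the deposited values only. The SD was 1.72, 2.01 and 1.76 in control replicates 1, 2 and 3 and 1.88, 2.12 and 1.96 in the activated replicates. Such a shared order of spread can also make these deviations correlate, so the check does not establish a shared origin. The pairing rests on the numbers in the sample titles and on this check. The fit with the replicate number as a block is therefore given where it changes a call. In simulated data with the block, 30% of genes changed 2-fold and 100% of those changed 4-fold were recovered, and 15 unchanged genes were called. Those simulated genes also varied independently, so these shares need not hold for the real data either.

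The 23 gene lists were fixed before the data were examined. They cover Wnt/beta-catenin feedback and target genes, Wnt pathway components, muscle stem cell and myoblast genes, myogenic commitment and fusion genes, sarcomere and contraction genes, cell cycle genes, the Notch pathway, the TGF-beta and BMP pathways and the extracellular matrix. They also cover markers of fibroblasts, smooth muscle and pericytes, endothelium, leukocytes, adipocytes, bone and cartilage, and neural and Schwann cells. The remaining lists hold cholesterol synthesis, oestrogen and aryl hydrocarbon receptor response, p53 response, unfolded protein and integrated stress response, interferon response, immediate early and sex-linked genes. Of the list symbols, 5 were matched through synonyms in the RefSeq table. Lists were tested against all other genes with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 23 lists, and again with an estimated correlation. The fry test asks whether a list's genes move on balance one way, and its mixed version whether they change in either direction. In simulated data with independent genes, a list shifted by 0.5 on the log2 scale was called and 0 of the 22 other lists were. In the real data the estimated correlation was 0.33 for sarcomere and 0.35 for cell cycle genes, so this simulation does not give the rate of false calls here. Other divisions of the 6 arrays into sets of 3 called 1 to 11 lists at the preset correlation. Each list's median change was also placed among 10000 random lists matched on mean expression in 50 bins.

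The named genes are Ctnnb1, Axin2, Lef1, Pax7, Myf5, Myod1 and Myog, the 12 highest and the 12 lowest genes, and up to 4 members of each list with the smallest p. Since fewer than 5 genes passed, the 12 genes per direction are those with the smallest unadjusted p, as the rule provides, and predicted genes, Rik, Mir and Snor names would have been skipped (0 occurred). Alternatives were repeated quantile normalization, median centring, a filter at the median level, all 24479 probe sets, an intensity trend or robust variance model, an unmoderated linear model, array weights, the replicate block, leaving out each array, averaging probe sets, a 1.5-fold minimum and an adjusted p under 0.01. Cyclic loess normalization, quantile normalization with the block, leaving out each pair, and the block with an estimated correlation were added after seeing the data. Each normalization was applied to all named probe sets before 1 was taken per gene. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Probe sets without a symbol were left out of the gene counts. In the fit over all 24479 probe sets, 0 of the 1198 unnamed ones passed an adjusted p of 0.05 by limma, and 96 had an unadjusted p under 0.05.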

Results

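The series asks how an active form of beta-catenin, the transcriptional effector of canonical Wnt signalling, alters gene expression in differentiating primary myoblasts. Recombination removes exon 3 of Ctnnb1, which encodes the phosphorylation sites that mark the protein for degradation. Gene expression was profiled in 3 control cultures (ethanol) and 3 activated cultures (4-hydroxytamoxifen). The 6 arrays had median log2 values between 4.04 and 4.36. The spread of values within an array (SD over all probe sets) was 1.72, 2.01 and 1.76 in control replicates 1, 2 and 3 and 1.88, 2.12 and 1.96 in the activated replicates. Across genes, arrays correlated at 0.892 to 0.949 within the control group at 0.948 to 0.959 within the activated group and at 0.862 to 0.962 between the groups, the highest between control replicate 2 and activated replicate 3. Control replicate 3 had the lowest mean correlation with the other arrays (0.896). Sex-linked transcripts did not separate the groups: the X-inactivation transcript Xist was at 2.91 ± 0.24 (SD, n = 3) in control and 2.84 ± 0.13 in activated cultures, and the Y-linked Eif2s3y at 7.56 ± 0.28 and 7.55 ± 0.15.

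Ctnnb1 (Entrez 12387) was measured at 8.54, 8.71 and 8.30 in control replicates 1, 2 and 3 and at 7.91, 8.79 and 8.91 in the activated replicates. The difference was 0.02 ± 0.31 (SE) on the log2 scale (limma, adjusted p = 0.988). Its sign turned to -0.35 after repeated quantile normalization and to -0.39 after cyclic loess. This probe set summarizes the whole gene, so its level does not check the loss of a single exon. Axin2 (Entrez 12006), a negative-feedback target of beta-catenin used as a readout of the pathway, was at 4.32 ± 0.44 (SD, n = 3) in control and 5.96 ± 0.53 in activated cultures, a 3.14-fold difference with each activated array above each control array. The adjusted p of Axin2 was 0.29 in limma and 0.0845 with the replicate block.

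No single gene passed an adjusted p of 0.05 in the comparison of activated with control cultures (limma, 0 of 23279 genes, smallest adjusted p = 0.0848), while 1830 genes had an unadjusted p under 0.05, of which 1034 were higher and 796 lower in activated cultures. For independent arrays chance alone would give 1164 at that level. The other 3 splits that part all 3 numbered pairs gave 222, 229 and 426. The splits that part only 1 pair gave 392, 784, 1145, 1500, 2266 and 2619, so some exceeded the real 1830. All these splits mix control and activated arrays, so a real group difference would add to their spread within sets. Their counts therefore do not set a chance level for the 1830 genes. The 3 activated arrays all lay above the 3 control arrays for 1257 genes and all below for 1723, together 12.8% of genes against 10% by chance for independent arrays. The count at an unadjusted p under 0.05 was 3066 without control replicate 2 and 907 without activated replicate 2. After median centring it was split into 1320 higher and 537 lower genes, and the centring moved the median change of all genes from -0.08 to 0.04. With the replicate number as a block, 3874 genes had an unadjusted p under 0.05 (2242 higher and 1632 lower). After adjustment 31 passed with the block, 28 rose and 3 fell, and all 31 moved the same way in each of the 3 pairs. The blocked fit selects genes with similar differences in the pairs, so this shared direction adds no support. The count of genes past the blocked fit was 0 when the arrays were first quantile-normalized again. It was 0 without pair 1, 0 without pair 2 and 492 without pair 3. Leaving out activated replicate 3 alone, without the block, gave 28 genes, of which 2 were among the 31.

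Of the 12 higher genes with the smallest p, Fst, Bmp2 and Gdf6 belong to the TGF-beta and BMP list, Timp3 to the extracellular matrix list and Xirp1 to the sarcomere list. Timp3, an inhibitor of metalloproteinases, had the largest difference among the 12, 4.03 ± 0.65 (SD, n = 3) in control and 8.43 ± 0.60 in activated cultures, or 21.1-fold. Fst, encoding follistatin, which binds activins and myostatin, was at 6.65 ± 0.43 and 9.60 ± 0.20, a 7.73-fold difference. The adhesion molecule Nrcam was at 3.69 ± 0.43 and 6.72 ± 0.18, and the BMP ligands Bmp2 and Gdf6 differed by 3.14 ± 0.38 and 2.92 ± 0.38 (SE) on the log2 scale. The long-chain acyl-CoA synthetase Acsl3 differed by 2.77, Myzap by 2.70, the ubiquitin ligase Herc3 by 2.63, the matrix protein Frem2 by 2.59, the actin-binding muscle protein Xirp1 by 2.58, Lrtm1 by 2.52 and the protein kinase A anchoring protein Akap6 by 2.02. None passed limma's unblocked test, where the adjusted p of these 12 and of the 12 lower genes ran from 0.0848 to 0.175. With the block, Nrcam, Fst, Myzap, Xirp1, Bmp2 and Acsl3 passed, each at an adjusted p of 0.0434.

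Of the 12 lower genes with the smallest p, 2 belong to the cell cycle list (Brca1 and Melk). Ska3, a component of the spindle and kinetochore complex, was at 6.11 ± 0.21 (SD, n = 3) in control and 4.20 ± 0.18 in activated cultures, and the mitotic kinesin Kif15 at 6.70 ± 0.10 and 4.09 ± 0.74. The spindle protein Hmmr had a log2 difference of -2.55 ± 0.38 (SE), the centromere proteins Cenph and Cenpu of -2.26 ± 0.34 and -1.71 ± 0.25, and the condensin subunit Smc2 of -2.15 ± 0.33. Ccdc18 differed by -1.92, Slc43a3 by -1.97, the nuclear lamina gene Lmnb1 by -1.67, the DNA repair gene Brca1 by -1.65, the kinase Melk by -1.55 and the cadherin Cdh6 by -1.42. With the block, Ska3 (adjusted p = 0.0479) and Ccdc18 (0.0487) fell. The third gene to fall with the block was Troap, a spindle-associated protein outside the naming rule and chosen after its values were seen, with a difference of -2.08 ± 0.18 (SE with block).

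**Figure D1:**
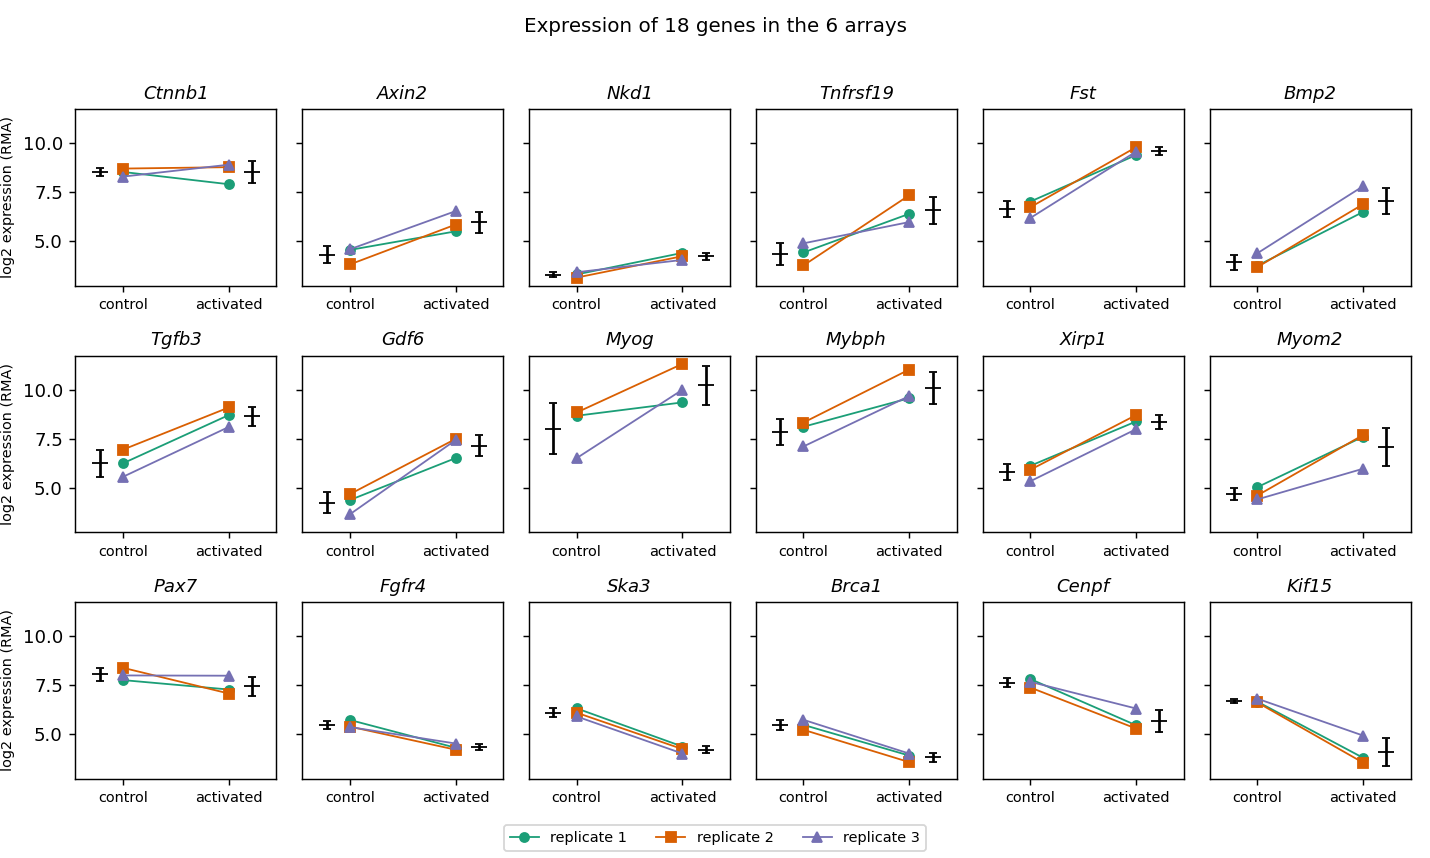
Log2 expression (RMA, vertical axis) of 18 genes in control and activated cultures; coloured lines join arrays with the same replicate number, and black bars give the mean ± SD of 3 arrays. Fst, Bmp2 and Xirp1 were higher and Ska3, Brca1 and Kif15 lower in each of the 3 activated arrays, while Ctnnb1 overlapped between the groups.

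Genes of the contractile apparatus rose as a list in camera's test with the preset correlation (adjusted p = 2.97e-29), a call lost with an estimated correlation (adjusted p = 0.250). Of 59 measured sarcomere and contraction genes 55 were higher in activated cultures, with a median log2 change of 1.54, and in 28 of them each activated array exceeded each control array. The 4 members with the smallest p were Xirp1, the M-band protein Myom2 (4.67 ± 0.32 in control and 7.08 ± 0.97 in activated cultures; SD, n = 3), the Z-disc actinin Actn3 (8.11 ± 0.32 and 9.92 ± 0.66) and the M-band protein Myom1 (5.07 ± 0.39 and 7.48 ± 1.03). No member passed over all genes in limma, 23 were higher when adjusted over the list alone (45 with the block), and with the block Xirp1 and, outside the naming rule, Srl, Actn2, Myoz2 and Trdn passed over all genes. The list median lay at percentile 100 of expression-matched random lists. The list mean was higher in each pair, by 1.24, 1.80 and 1.35.

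The list of myogenic commitment and fusion genes also rose in camera's test (adjusted p = 9.43e-13), a call lost with an estimated correlation (adjusted p = 0.250). It had 34 of 40 members higher and a median log2 change of 0.79 (31 members and 0.46 after quantile normalization). Musk, the receptor kinase of the neuromuscular junction, was at 7.60 ± 0.20 in control and 8.80 ± 0.31 in activated cultures (SD, n = 3), and Mybph, a myosin-binding protein, at 7.85 ± 0.65 and 10.10 ± 0.82. Without the block these were the 2 members past the test adjusted over the list alone, with 0 over all genes. With it, 24 members were higher over the list alone, and Klhl41 and the transcription factor Mef2c, both outside the naming rule, passed over all genes. The list median lay at percentile 100 of expression-matched random lists. The receptor Erbb3 differed by 1.75 ± 0.42 (SE) and the transcription factor Mef2a by 0.99 ± 0.26 (0.61 after quantile normalization and 0.50 after cyclic loess). Among the myogenic regulators, Myog was at 8.01 ± 1.30 and 10.24 ± 1.00 (limma, adjusted p = 0.502; log2 difference 2.22, and 1.47 without control replicate 3), Myod1 at 9.33 ± 0.59 and 9.48 ± 0.73 (0.918) and Myf5 at 4.66 ± 0.62 and 5.04 ± 0.37 (0.784). The sign of the Myod1 difference turned to -0.20 after quantile normalization and to -0.32 after cyclic loess.

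Cell cycle genes fell as a list in camera's test (adjusted p = 6.42e-20), a call lost with an estimated correlation (adjusted p = 0.273). Of 58 measured members 52 were lower in activated cultures, with a median log2 change of -1.18, and in 31 each activated array lay below each control array. Cenpf, a kinetochore protein of dividing cells, was at 7.63 ± 0.22 in control and 5.68 ± 0.55 in activated cultures (SD, n = 3), and the spindle checkpoint kinase Ttk at 6.57 ± 0.28 and 4.62 ± 0.58. None passed over all genes in limma, and 23 were lower when adjusted over the list alone (34 with the block). The list median lay at percentile 0 of expression-matched random lists. The list mean differed by -1.27 in pair 1, by -1.80 in pair 2 and by -0.34 in pair 3.

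Muscle stem cell and myoblast genes did not shift as a list: 15 of 31 members were higher and 16 lower (camera, adjusted p = 0.532). The fry mixed test, which asks for changes in either direction, gave an adjusted p of 0.0176. That test was under 0.05 for 10 of the 23 lists, so the result is not particular to this list. Fgfr4, a fibroblast growth factor receptor of myoblasts, was at 5.49 ± 0.20 in control and 4.34 ± 0.16 in activated cultures (SD, n = 3) and was the only member past the test adjusted over the list alone without the block, with 0 over all genes. With the block 7 members were higher and 2 lower over the list alone. The adhesion molecule Vcam1 differed by -1.38 ± 0.38 (SE), the intermediate filament gene Des by 1.56 ± 0.36 (1.02 after cyclic loess) and the cadherin Cdh15 by 1.03 ± 0.29. Pax7, the transcription factor that marks muscle stem cells, was at 8.05 ± 0.32 and 7.45 ± 0.48 (limma, adjusted p = 0.688).

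The list of Wnt/beta-catenin feedback and target genes rose in camera's test (adjusted p = 0.00163), which was lost with an estimated correlation (adjusted p = 0.406). The list was evenly divided in sign, 17 members higher and 15 lower, with a median log2 change of 0.10 (percentile 98.0 of expression-matched random lists) and a mean of 0.37. In 8 members each activated array exceeded each control array, and in 0 the reverse held. Members adjusted over the list alone numbered 6 (0 over all genes): Axin2, Fst, the receptor Tnfrsf19 (4.36 ± 0.57 in control and 6.58 ± 0.70 in activated cultures; SD, n = 3), the feedback inhibitor Nkd1 (3.28 ± 0.14 and 4.22 ± 0.18), and, outside the naming rule, Bmp4 and Ephb3, with log2 differences of 1.01 and 1.41. With the block, 6 members were higher and 1 lower over the list alone, and Fst passed over all genes. The nuclear partner Lef1 was at 5.29 ± 0.52 and 6.15 ± 0.88 (limma, adjusted p = 0.697), a log2 difference of 0.86 that was 0.35 without activated replicate 3. Without control replicate 2 the adjusted p of the list was 0.0526. Wnt pathway components had 27 of 55 members higher and 28 lower (camera, adjusted p = 0.33). They include ligands, receptors, secreted modulators, the degradation complex and nuclear factors. Among them the receptors Fzd1 and Fzd2 differed by 0.81 ± 0.22 and 0.94 ± 0.39 (SE), the ligand Wnt9a by 0.88 ± 0.28 and the kinase Csnk1a1 by 0.86 ± 0.37 (0.46 without control replicate 3 and 0.48 after quantile normalization). Outside the naming rule and chosen after their values were seen, the nuclear factors Tcf7l2 and Tcf7l1 differed by -0.87 and -0.84 (-1.17 and -1.08 after quantile normalization).

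TGF-beta and BMP pathway genes rose as a list (camera, adjusted p = 3.07e-05), and this call too was lost with an estimated correlation (adjusted p = 0.250). The median change of the 49 members was 0.12 and their mean 0.42 (0.05 and 0.33 after quantile normalization, with 25 members higher against 31 as deposited), and the median lay at percentile 77.6 of expression-matched random lists. In 12 members each activated array exceeded each control array. Bmp2, Fst, Gdf6, Tgfb3 and Inhba, the last outside the naming rule, were higher when adjusted over the list alone (5 members, 0 over all genes). Tgfb3 was at 6.25 ± 0.70 in control and 8.64 ± 0.50 in activated cultures (SD, n = 3). With the block 11 members were higher over the list alone, and Bmp2, Tgfb3 and Fst passed over all genes. Fst, Bmp4 and Id2 belong to both this list and the Wnt target list. Notch pathway genes, with 9 of 27 members higher, did not shift (camera, adjusted p = 0.631). The largest difference among the named Notch members was that of Hes6, 1.71 ± 0.70 (SE) and 0.95 without activated replicate 2. Hey1 differed by 0.63, Hes7 by -0.92 and Notch4 by -0.56 (-0.37 without control replicate 3).

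Macrophage and leukocyte markers fell as a list (17 of 19 lower, median log2 change -0.30, camera adjusted p = 0.00309), which was lost with an estimated correlation (adjusted p = 0.474), after cyclic loess (0.0504) and after quantile normalization with the block (0.0556). Their median control level was 3.71, at percentile 37.8 of all genes, and the 4 with the smallest p were Fcer1g (-0.67 ± 0.25, SE), Csf1r (-0.54), C1qb (-0.54) and Laptm5 (-0.45). After cyclic loess Csf1r was at -0.33 and C1qb at -0.34, and without control replicate 3 C1qb was at -0.33. Endothelial markers fell with 13 of 15 lower (median -0.29, adjusted p = 0.0448, and 0.474 with an estimated correlation). This call ended with the block (adjusted p = 0.0605), after median centring (0.0838) and after quantile normalization (0.561). It also ended without control replicate 1 (0.0516), 2 (0.0619) or 3 (0.143) and without activated replicate 2 (0.147) or 3 (0.101), and held without activated replicate 1 (0.0265). Esam, Egfl7, Vwf and Tek differed by -0.37 to -0.29, and by -0.24 to -0.11 after quantile normalization. Without control replicate 2 Egfl7 was at -0.21 and Esam at -0.57, and without control replicate 3 Vwf was at -0.21. Fibroblast and fibro-adipogenic progenitor markers had 15 of 19 members lower (10 after quantile normalization) and were not called (adjusted p = 0.261): Fbln1 differed by -1.11, Col3a1 by -0.95, Cd34 by -0.62 and Thy1 by 1.17. Col3a1 was at -0.53 without activated replicate 1, and Cd34 at -0.36 without control replicate 2. Smooth muscle and pericyte markers (adjusted p = 0.353) went both ways, with Rgs5 at -1.78 ± 0.55 (SE), Acta2 at 1.08 ± 0.39 (0.69 after quantile normalization) and Tagln at 0.68 ± 0.29 (0.44 without control replicate 1). Neural and Schwann cell markers were not called (camera, adjusted p = 0.408). Of 13 measured members 9 were lower, with a median log2 change of -0.37 (-0.19 after quantile normalization). The median lay at percentile 0.52 of expression-matched random lists. One member, the neuronal tubulin Tubb3, was higher when adjusted over the list alone (0 members with the block). It was at 5.69 ± 1.66 in control and 8.84 ± 0.32 in activated cultures (SD, n = 3), and Mbp, Sox10 and Dcx differed by -0.69, -0.52 and 0.42.

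The differences between groups varied with expression level across all genes. Genes with a mean level of 3 to 4 had a median log2 change of -0.20, and those at 8 to 9 of 0.41. After repeated quantile normalization these medians were -0.02 and 0.08. The median over all genes was -0.08 as deposited and -0.01 after quantile normalization, and the share of higher genes 40.3% and 48.2%. The arrays' own spread averaged 1.83 ± 0.16 (SD, n = 3) in control and 1.99 ± 0.12 in activated cultures. Against expression-matched random lists, the medians of the leukocyte and endothelial lists lay at percentiles 2.59 and 6.67.

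**Figure D2:**
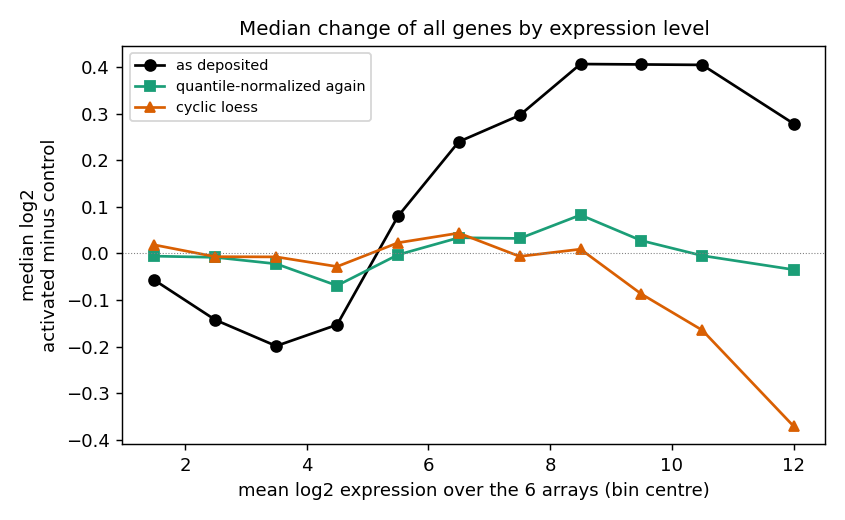
Median log2 difference between activated and control cultures (vertical axis) for genes binned by mean log2 expression over the 6 arrays (horizontal axis), for the values as deposited and after 2 further normalizations. As deposited, the median ran from -0.20 at a level of 3 to 4 to 0.41 at 8 to 9.

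**Figure D3:**
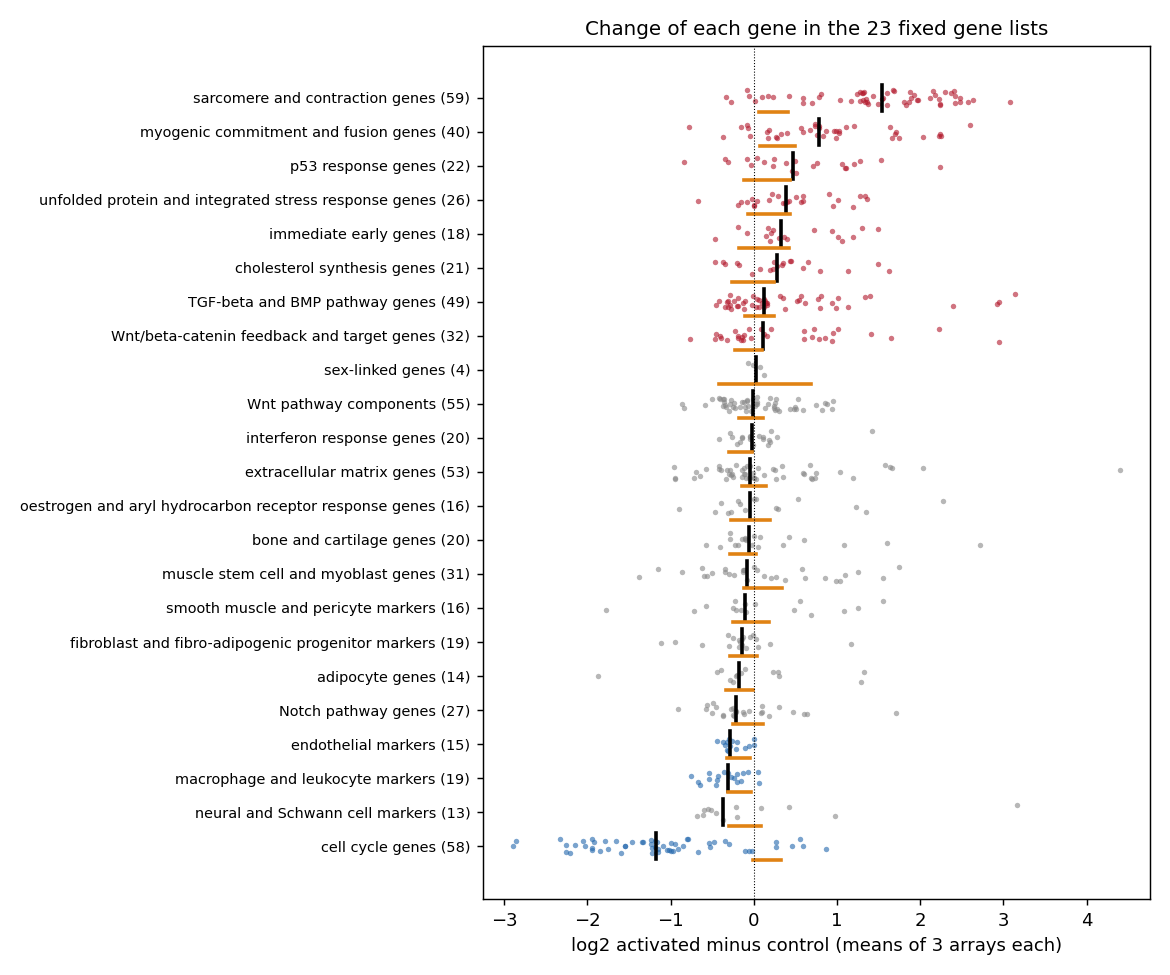
Log2 difference between activated and control cultures (horizontal axis) for each member (dots) of the 23 gene lists, with the number of measured members in brackets. Black bars are list medians, orange bars span the central 95% of medians of expression-matched random lists, and red and blue mark lists called up and down by camera at an adjusted p under 0.05 with the preset correlation. The sarcomere list has a median of 1.54 and the cell cycle list of -1.18.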

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

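Cyclic loess, quantile normalization with the block, the block with an estimated correlation and leaving out each pair were chosen after seeing the data. The number of genes past an adjusted p of 0.05 was 0 by limma (1830 at an unadjusted p under 0.05) and by the unmoderated linear model (1456). It stayed 0 under every alternative run except the replicate block (31 genes, 28 higher and 3 lower), leaving out activated replicate 3 (28), and the block without pair 3 (492). Leaving out each array gave 0 to 28 genes, 0 to 18 higher and 0 to 10 lower. The blocked count was 0 without pair 1, 0 without pair 2 and 492 without pair 3, the last with 4 arrays and 1 residual degree of freedom per gene, and 0 with quantile normalization and the block. The block ended the call of the endothelial list and of no other list, and added calls for 10 of the named genes. Of the 11 lists called with the preset correlation, 7 lists were called after cyclic loess and 0 with an estimated correlation, with fry, or with the block and an estimated correlation. With an estimated correlation the adjusted p was 0.406 for Wnt targets, 0.250 for the commitment, sarcomere and TGF-beta lists and 0.273 for cell cycle genes. With fry it was 0.167 for Wnt targets and 0.124 for the other 4, and with the block and an estimated correlation 0.37 for Wnt targets and TGF-beta, 0.258 for commitment and sarcomere genes and 0.404 for cell cycle genes. The sarcomere, commitment, cell cycle and TGF-beta lists kept their calls under each normalization, the filter, the block and each left-out array. Wnt targets ranged from 9.52e-05 to 0.0526 over left-out arrays, the highest without control replicate 2. Signs turned for some results not called in the values as deposited. Ctnnb1 was -0.35 after quantile normalization, with or without the block, -0.39 after cyclic loess and -0.17 to 0.33 over left-out arrays. In the same order Myod1 was -0.20, -0.32 and -0.22 to 0.52, and Uty -0.10, -0.087 and -0.22 to 0.24. Xist was 0.11, 0.097 and -0.20 to 0.012, with 0.061 after median centring. Kdm5d was -0.018 after quantile normalization and -0.16 to 0.43 over left-out arrays, and Eif2s3y 0.12 after median centring and -0.14 to 0.14. The direction of the muscle stem cell list turned after quantile normalization (adjusted p = 0.799, 0.757 with the block) and cyclic loess (0.686), and its adjusted p was 0.0653 to 0.849 over left-out arrays. The adipocyte list turned under the same 3 settings (0.561, 0.455 and 0.536) and with the filter (0.94), with 0.441 to 0.993 over left-out arrays, and the sex-linked list likewise (0.781, 0.726, 0.704 and 0.94; 0.563 to 0.993). With the filter, Wnt components (0.967) and neural markers (0.94) turned too. Over left-out arrays the Notch list turned (0.114 to 0.957), as did the matrix list (0.0123 to 0.776). Of the 112 named genes, the difference moved over 1.5 times for 26 when 1 array was left out and for 23 with quantile normalization, median centring or cyclic loess. Averaging a gene's probe sets changed no call, but only 2 symbols had several probe sets, so this checks almost nothing. The causes of these changes were not tested. The files give no detection calls, so how far dim genes stand above background is unknown.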

Other observations

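The tests on the leukocyte and endothelial lists and the count of splits for genes past an adjusted p were chosen after their results were seen, as was cyclic loess. Stress and immediate early genes were also called higher as lists in activated cultures. The medians of the unfolded protein and immediate early lists lay inside the central 95% of expression-matched random lists, at percentiles 95.1 and 92.1, and that of the p53 list at 98.5. Of 22 p53 response genes 17 were higher (camera, adjusted p = 5.16e-05, and 0.273 with an estimated correlation), among them the cyclin-dependent kinase inhibitor Cdkn1a at 9.16 ± 0.78 (SD, n = 3) in control and 11.39 ± 1.24 in activated cultures, the death receptor Fas (2.30-fold), Eda2r (2.41-fold) and Plk2 (2.15-fold). Cdkn1a is also a commitment gene of myoblasts and stands in that list too. Immediate early genes had 15 of 18 members higher (adjusted p = 2.66e-05, and 0.253 with an estimated correlation), with log2 differences of Dusp1 at 1.49, Klf4 at 1.30 and Egr1 at 1.02. Unfolded protein and integrated stress response genes had 21 of 26 members higher (adjusted p = 5.16e-05, and 0.474 with an estimated correlation), with fold differences of 2.57 for the cystine transporter Slc7a11, 2.42 for Ppp1r15a, 2.29 for Atf3 and 1.93 for Sel1l (log2 0.95, and 0.63 without control replicate 3). This call ended after cyclic loess (0.0669; 6.45e-07 to 0.474 over all 16 alternatives). Atf3 and Slc7a11 were higher when adjusted over that list alone. None of these genes passed over all genes in limma. With the block, the members higher when adjusted over the list alone were 7 p53, 7 immediate early and 6 unfolded protein response genes.

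Cholesterol synthesis genes had 15 of 21 members higher (camera, adjusted p = 0.024, and 0.474 with an estimated correlation), with log2 differences of Ebp at 1.62, Hsd17b7 at 1.49, Cyp51 at 1.14 and Nsdhl at 0.80. Without activated replicate 2 Ebp was at 0.71 and Nsdhl at 0.45, and without activated replicate 3 Ebp was at 2.44. In camera's test the call ended after quantile normalization (0.0915), median centring (0.0639) and cyclic loess (0.0909) and with the filter at the median level (0.250). It also ended without control replicate 3 (0.129) and without activated replicate 2 (0.275). Over all 16 alternatives the adjusted p of this list ran from 0.00606 to 0.475. Oestrogen and aryl hydrocarbon receptor response genes split 8 to 8 (adjusted p = 0.532), with Cyp1b1 at 2.27 ± 0.61 (SE), Ahr at 1.23 ± 0.24, Esr1 at 0.53 and Greb1 at -0.89. The fry mixed test gave that list an adjusted p of 0.00628 and was under 0.05 for 10 of the 23 lists, so this is not particular to a drug-response list. Ahr was higher when adjusted over the list alone, and 3 members were with the block. Every activated culture received 4-hydroxytamoxifen and every control culture ethanol, so a response to the drug or to the recombinase and a response to active beta-catenin have the same design. Bone and cartilage genes were not called (adjusted p = 0.268): the osteoblast factor Sp7 was at 4.89 ± 1.35 and 7.60 ± 0.61 (SD, n = 3), and Tnfrsf11b, Dlx3 and Phex differed by 1.60, 1.09 and -0.57. Phex was at -0.31 without control replicate 1. Extracellular matrix genes were not called either (adjusted p = 0.116), though without activated replicate 1 or 2 they were called higher (0.0123 and 0.0132), and without activated replicate 3 their direction turned (0.776). Timp3 and Adamts1 (1.66) were higher when adjusted over that list alone, Adamts5 (2.03) passed over all genes with the block, and Timp1 differed by 1.19 (0.77 after quantile normalization). Without control replicate 2 the difference of the adipocyte gene Lpl was -0.85 against -1.87 with all arrays, and that of Cd36, 1.32 with all arrays, was 0.72 without activated replicate 2 and 2.31 without activated replicate 3. Adipocyte genes (adjusted p = 0.994; Lpl -1.87, Cd36 1.32, Pparg 1.29, Adipoq -0.44), interferon response genes (0.567; Xaf1 1.42, Mx1 -0.42, Isg15 0.28, Oasl1 -0.26) and sex-linked genes (0.759; Kdm5d 0.12, Uty 0.07) were not called. Oasl1 was at -0.11 without control replicate 1 and -0.41 without control replicate 2. After quantile normalization Oasl1 was at -0.08, Mx1 at -0.28 and Isg15 at 0.46. For the muscle stem cell, Wnt component, matrix, smooth muscle, bone, oestrogen and interferon lists the median was below 0 while the mean and camera's direction were above it, and for neural markers the mean was above 0 while the median and the test were below it. After quantile normalization the medians of the smooth muscle, bone and interferon lists were above 0.

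The lower endothelial and leukocyte markers are a candidate consequence of the arrays' dynamic range, since the spread of values averaged 1.83 in control and 1.99 in activated arrays and was narrower in the control array of each pair, and dim genes as a class were lower in activated cultures. For endothelial markers the median lay at percentile 6.67 of expression-matched lists and the call ended after quantile normalization, as that explanation predicts. The predictions for both marker lists were written after the results were seen, so a match is no independent test. For leukocyte markers the median lay at percentile 2.59, above the limit of 2.5, yet the list stayed called lower after quantile normalization (adjusted p = 0.0425; 0.00207 to 0.474 over all 16 alternatives), so the explanation stays open. Fewer cells of either type in activated cultures cannot be told apart from this. The median control levels lay at percentile 37.8 (leukocyte) and 30.2 (endothelial) of all genes, but signals of different probe sets do not compare abundance between genes, so these levels do not weigh for or against fewer cells. Of the leukocyte markers, Cd68 had the highest control signal, 5.75 ± 1.37 (SD, n = 3), and was at 5.69 ± 0.85 in activated cultures. Next came Cd53, at 5.13 ± 0.81 in control and 4.37 ± 0.08 in activated cultures, and Fcer1g, at 4.97 ± 0.36 and 4.30 ± 0.15. Cd68 and Cd53 were chosen after their values were seen. The endothelial marker with the highest control signal was Egfl7, at 4.77 ± 0.28 and 4.43 ± 0.14.

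The higher sarcomere genes and lower cell cycle genes were set against the same explanation. Their medians were beyond those of all 10000 expression-matched lists (a tail share of 0 percent for array dynamic range). Both lists stayed called in the same direction after quantile normalization, with medians of 1.35 and -1.34. These values argue against the arrays' dynamic range as the whole cause. They do not weigh against chance, since the random lists lack the estimated correlation between members (0.33 for sarcomere and 0.35 for cell cycle genes). Control replicate 3, the array least like the others, does not carry the pattern alone: without it the sarcomere median was 1.18 (76.6% of its value) and the cell cycle median -1.23. The gap between the 2 list medians was 2.72, and 1 of the 10 splits of the 6 arrays, the real one, reached it (highest other 2.08, and 1.48 among the splits that part all 3 pairs), but 10 splits are too few for a share under 0.05. Active beta-catenin, the drug and the recombinase stay open as sources of this pattern, since the design does not separate them. A chance difference between the cultures stays open too. The splits cannot exclude it, and neither list was called with an estimated correlation (camera, adjusted p = 0.250 for sarcomere and 0.273 for cell cycle genes).

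Some splits that keep numbered pairs together gave as many calls as the groups did. At an unadjusted p under 0.05, 3 of the 10 splits gave at least the real 1830 genes, and the highest other gave 2619. That split set control replicates 1 and 3 and activated replicate 1, the 3 arrays with the narrowest spread, against the rest, and also called 11 lists, as the real split did (2 of 10 splits reached 11). The splits above 1830 part only 1 pair. Of the 4 splits that part all 3 pairs, the real one gave the most genes and lists, and the others at most 426 genes and 8 lists. With 0 genes past an adjusted p of 0.05 in the real split and in the highest other, all 10 splits tied. With the block, 1 of these 4 splits, the real one, gave 31 genes, and the highest other gave 0. Neither 10 nor 4 splits can give a share under 0.05.

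Arrays with the same number had correlated deviations from the group means, and whole profiles followed the numbers in part. Activated replicates 1 and 3 correlated more with control replicate 2 (0.952 and 0.962) than with the control arrays of their own number (0.938 and 0.930). Of the activated arrays, only replicate 2 correlated most with the control array of its number (0.953). Seen from the control arrays, replicate 1 correlated most with activated replicate 1 (0.938) and replicate 3 with activated replicate 3 (0.930). Control replicate 2 correlated most with activated replicate 3 (0.962). At an unadjusted p under 0.05, 4492 genes (19.3%) differed between the 3 numbered pairs, and 0 passed an adjusted p of 0.05 (limma). Actb, often used as a reference gene, was at 7.67 and 7.71 in the control and activated arrays numbered 1 and between 10.17 and 11.99 in the other 4. Tmsb15a was at 3.18 and 5.55 in the arrays numbered 3 and between 7.33 and 9.97 in the others, and the sarcomere gene Myoz2 was at 5.37 and 7.43 against 8.09 to 10.91. The last 2 genes were also higher in the activated array of each pair and passed with the block (limma, adjusted p = 0.0434). Actb, Tmsb15a and Myoz2 were chosen after their values were seen. Of the 31 genes that passed with the block, 20 were in none of the lists. Among these, chosen after their values were seen, the log2 differences were 2.82 for Xirp2, 2.60 for Dclk1, 2.13 for Nrap and 2.13 for Ppargc1a, a coactivator of mitochondrial gene expression.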
